A study of Mus musculus with 173 samples.

How the data were processed

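RNA was measured in 11 tissues of 16 mice aged 6 months, 8 heterozygous for the Q175 allele and 8 wild type, with 4 females and 4 males of each genotype. The 173 libraries were used one by one, 15 in gonadal white adipose tissue, 14 in skin and 16 in each other tissue. Per the labels' protocols, tissue was flash frozen, total RNA was taken up with a column kit, and polyadenylated RNA was made into libraries by standard Illumina protocols. The labels do not state whether the libraries keep strand, so reads of overlapping genes on the 2 strands cannot be told apart. CASAVA 1.8.2 is named per the submitters' processing notes. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

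The authors deposited 2 tables. One holds estimated (expected) counts per Ensembl gene and library, not scaled between libraries: 31.3% of the values (mean over libraries) are not whole, and the deposited counts sum to 28 to 48 M (mega) per library. The other holds FPKM values, which the authors made by scaling to gene length and to the library total: checked on 10144 genes, the ratio of counts to deposited FPKM scaled with the library total, with a median factor of 1 in each library, 173 of 173 columns matched their own library best, and the lowest such correlation was 0.986. Its gene list has 38561 entries, of which 36639 (95%) were given a symbol by their Ensembl identifier. CPM values (counts scaled to the library total) and all log2 fold changes here were computed from the deposited estimated counts. The CPM of single genes given as mean and SD are on the TMM scale, while summed CPM of lists and the CPM of single libraries in the checks are on the plain library total. The estimated counts were rounded to whole numbers for the tests.

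Each tissue was tested apart in edgeR 4.0.16: TMM scaling, filterByExpr with genotype as the group, robust quasi-likelihood F-tests with sex and genotype as terms, and Benjamini-Hochberg adjustment over the genes tested, with genes called at an adjusted p under 0.05. Standard errors of log2 fold changes come from the same models, and CPM values are given as mean and SD. The difference in response between sexes was tested with an interaction term in the same way. The difference in response between tissues was tested with limma 3.58.1 (voom, with the correlation of libraries from 1 animal estimated). Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 473 list and tissue pairs. Members were also adjusted over the list alone. Summed CPM of a list's members served as a measure of transcripts from other tissues. R 4.3.3, DESeq2 1.42.0, the data.table package (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.

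The tests, the 50 gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. Named genes in each tissue are Htt, then up to 8 genes with the largest rise and 8 with the largest fall among those called, with a mean of at least 1 CPM and a single direction in both sexes, then up to 4 members with the smallest p of each list that passed or held a called member. Genes without an established name (clone and predicted gene symbols) are counted and not named. Some genes that the rule selects are not reported here by name, and they stay in the counts and list tests. Across tissues the rule takes genes called in at least 4 tissues with a single direction, up to 20. Genes named outside this rule, chosen after their values were seen, are 2310065F04Rik in gastrocnemius, the genes with a sex difference in gonadal adipose, Smoc1 and Acy3 as genes with both directions, and Atraid, Prkag2 and Galnt11 as genes near Htt.

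The models were tested on simulated counts drawn with the means, dispersions and library sizes of each tissue, with 200 genes changed, 100 of them 1.5-fold and 100 of them 2-fold. The 1.5-fold changes were recovered in 50 of 100 cases in brown adipose, 47 in gonadal adipose, 18 in intestinal adipose, 83 in brainstem, 78 in cerebellum, 80 in hippocampus, 69 in hypothalamus/thalamus, 52 in corpus callosum, 77 in gastrocnemius, 78 in heart and 39 in skin. The 2-fold changes were recovered in 77, 78, 44, 97, 92, 89, 89, 89, 88, 92 and 63 of 100 in that order. False calls numbered 3 to 14.

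The alternatives fixed in advance were RLE size factors, DESeq2, no filter on low counts, no sex term, a replicate block, the lane code of the library names as a term, limma on log2 of the deposited FPKM plus 1, voom over all tissues, and leaving out each library in turn. The L number of the library names was read as a lane, which no source states, and library names without a D part were pooled as 1 level. Pooled libraries are 14 of 16 in hippocampus and in corpus callosum and 11 of 16 in brainstem and in hypothalamus/thalamus, so the term adjusts for little there. For list tests the correlation was also estimated for each list. Alternatives added after the data were seen leave out libraries with transcripts of other tissues or libraries that stand apart, add a list sum as a term, or remove from each library the trend of its deviations with transcript length and GC content (natural splines with 4 degrees of freedom, GENCODE mouse transcripts). Genotype was also reassigned in splits of the animals that keep the sexes balanced: 100 of the 1225 possible, the real one included, and 40 for the test between tissues.

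The sex labels were checked: Xist was at least 188 CPM in female and at most 26.6 CPM in male libraries, and Ddx3y at most 0.621 CPM in female and at least 54.6 CPM in male libraries. No library repeats another within a tissue and group. No library was left out of the tests reported first. Per the labels, wild-type mice were housed with mice of the Q20 line and carry that line's animal codes, so colony and housing were not modelled, being the same contrast as genotype.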

Results

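Polyadenylated RNA was sequenced from 11 tissues of 16 C57BL/6 mice aged 6 months: 8 heterozygous Q175 mice, which carry an expanded run of 175 CAG codons in the mouse huntingtin gene Htt, and 8 wild-type mice, each genotype with 4 females and 4 males. The 173 libraries give 8 Q175 and 8 wild-type libraries per tissue, except gonadal white adipose tissue with 7 wild-type libraries and skin with 6. Library totals ran from 28 to 48 M (mega) estimated counts. The survey asks which tissues outside the striatum and cortex respond to the expanded allele. Per the labels, the Q175 mice were housed with Q175 mice and the wild-type mice with mice of the Q20 line, whose animal codes they carry, so genotype, housing and breeding colony cannot be separated in any comparison here. Changes are log2 fold changes of Q175 over wild type with their standard errors, from edgeR with sex as a term, and p-values are Benjamini-Hochberg adjusted unless called unadjusted.

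Htt, the modified gene, had a lower level in Q175 mice in 11 of 11 tissues. The fall passed the test in 4 of them: the change was -0.45 ± 0.04 in heart (adjusted p = 1.36e-05; 22 ± 1.28 against 30 ± 1.65 CPM, SD), -0.40 ± 0.045 in gastrocnemius (adjusted p = 0.0019), -0.58 ± 0.15 in hippocampus (adjusted p = 0.0387) and -0.21 ± 0.042 in cerebellum (adjusted p = 0.00182). The hippocampal call was lost without any one of 13 of the 16 libraries, all but Q175 females 2 and 3 and wild-type male 4 (adjusted p from 0.0503 to 0.0798). Q175 females 3 and 4 held 80.9 and 93.2 CPM of Htt in hippocampus, against 145 to 206 CPM in the other Q175 libraries: without both the change was -0.36 (adjusted p = 0.00641), and with the trend of transcript length and GC content removed it was -0.37 (adjusted p = 2.28e-06). With the lane code as a term the hippocampal and gastrocnemius calls were lost (adjusted p = 0.107 and 0.101), as they were without a sex term (0.0636 and 0.0701), on the deposited FPKM values (0.0506 and 0.254) and with the replicate block (0.0582 and 0.0909). The hippocampal call was also lost without the filter on low counts (0.0856). The changes themselves stayed near those given, at -0.62 to -0.55 in hippocampus and -0.40 in gastrocnemius, except -0.20 on FPKM values in gastrocnemius. With voom over all tissues the calls in heart, gastrocnemius and cerebellum were lost (adjusted p = 0.776, 0.991 and 0.983) at changes of -0.43, -0.39 and -0.21, and calls were gained in hypothalamus/thalamus and corpus callosum (0.00455 and 0.000963). DESeq2 gained corpus callosum (adjusted p = 0.0324) and the lane code brainstem (0.00381). A call was gained without wild-type male 1 in brown adipose (adjusted p = 0.00196) and without wild-type female 3 in brainstem (adjusted p = 0.00269). In 9 tissues its unadjusted p was under 0.05, and the difference in its change between tissues did not pass (adjusted p = 0.18). The smallest change by this test was -0.11 ± 0.12 in gonadal adipose, where it was 0.07 on the deposited FPKM values, -0.31 with the lane code as a term and -0.45 (adjusted p = 0.000568), the largest fall of the 11 tissues in that setting, with the length and GC trend removed. With the length and GC trend removed, Htt was called in 8 tissues. Abhd1, whose gene lies near Htt in gene order, was called in more tissues than any other gene: it rose in 9, by 1.27 in gonadal adipose up to 2.71 ± 0.30 in heart (adjusted p = 0.0021), with an unadjusted p under 0.05 in 11. Its rise differed between tissues by the voom fit over all tissues (adjusted p = 7.28e-05). In a single Q175 male Abhd1 lay within the wild-type range in 11 of 11 tissues, while 75 of the 77 libraries of the other 7 Q175 mice lay above the highest wild-type library of their tissue. The level of Htt in that male was nearer the Q175 mean than the wild-type mean in all but 3 tissues. By the measure used for Abhd1, its Htt also lay within the wild-type range in 8 of 11 tissues. The exceptions among the 77 were gonadal adipose Q175 male 2 (5.37 CPM, highest wild-type library 5.42) and skin Q175 female 4 (2.22 CPM, wild type 1.45 to 2.81). That skin library also held 64.7 CPM of Htt, above each wild-type skin library (42.2 to 63.1 CPM). In the other tissues of that female Abhd1 lay above the wild-type range, and whether the skin library carries the right label was not tested.

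**Figure D1:**
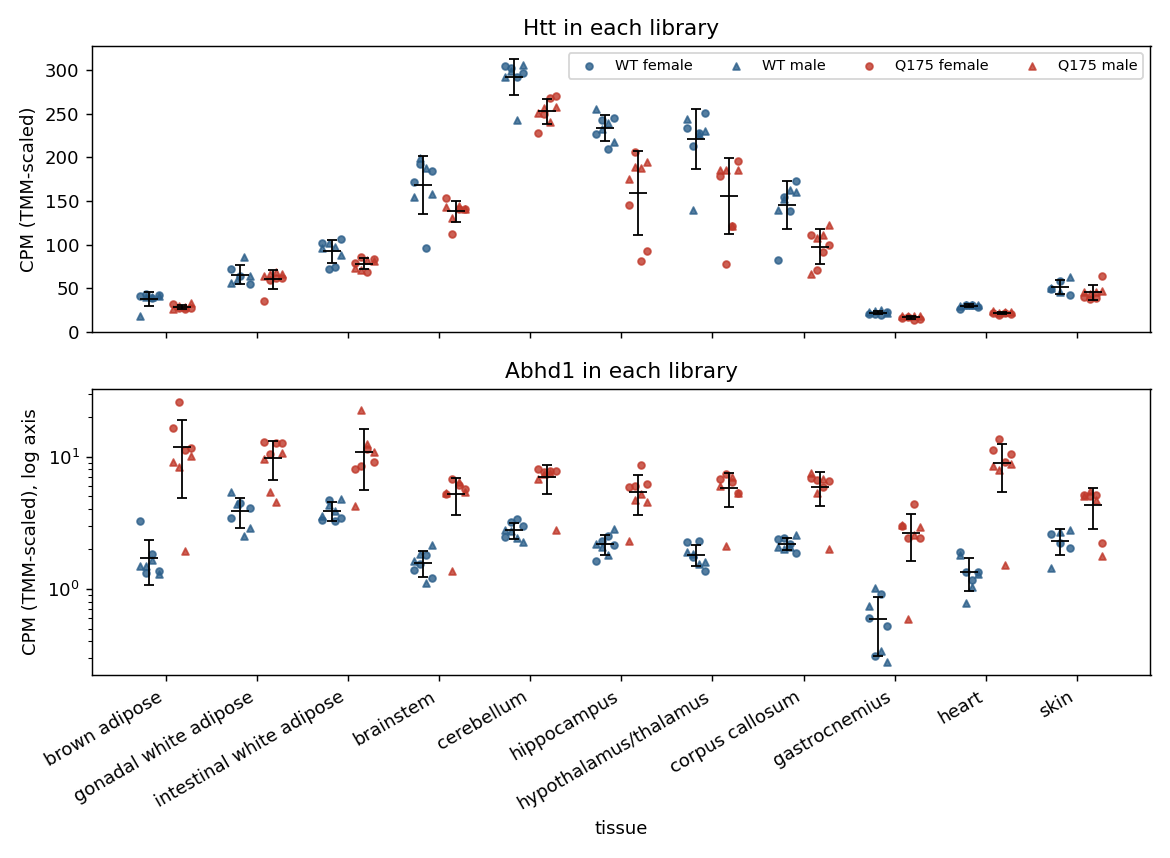
CPM of Htt (upper panel) and of Abhd1 (lower panel, log axis) in each library by tissue, with group means and SD as bars. Htt means were lower in Q175 in 11 of 11 tissues, and the lowest Q175 point for Abhd1 is the same male in each tissue.

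The number of genes called at an adjusted p under 0.05 ran from 0 in intestinal white adipose tissue to 5148 in gonadal white adipose tissue. Cerebellum had 2572, skin 1077, brown adipose 790, hippocampus 743, brainstem 509 and hypothalamus/thalamus 96. Corpus callosum had 9, heart 8 and gastrocnemius 3. Of 473 tests of gene lists fixed before the data were examined, 166 passed with camera at a preset correlation of 0.01. Only cholesterol synthesis in brainstem also passed with an estimated correlation, so each other list call below is lost with it.

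**Figure D2:**
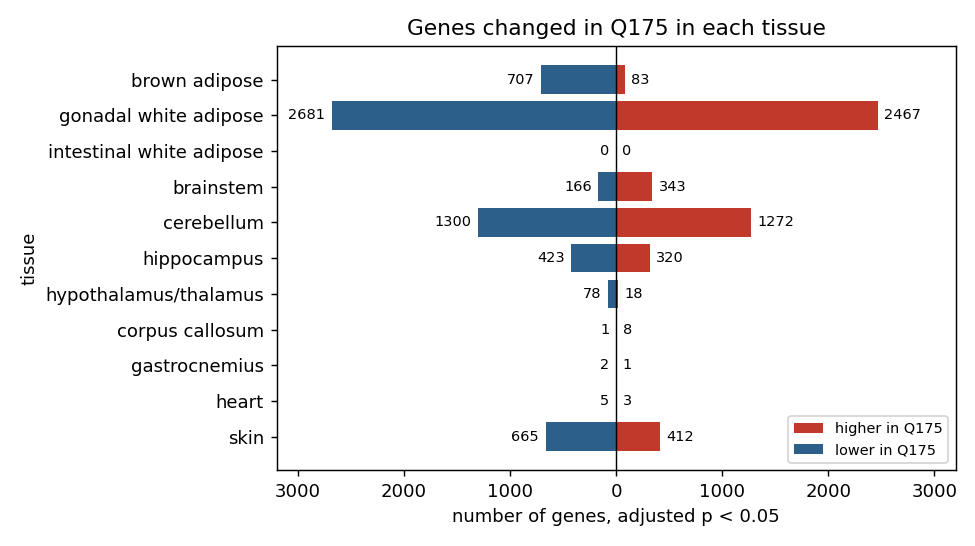
Number of genes called higher (right) and lower (left) in Q175 in each tissue at an adjusted p under 0.05, edgeR. Gonadal white adipose tissue and cerebellum had the longest bars, at 5148 and 2572 genes, and intestinal white adipose tissue had 0.

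In brainstem (8 against 8), 343 genes rose and 166 fell (84 genes in all with voom over all tissues). Cholesterol synthesis genes fell: 21 of 25 passed, 22 adjusted over the list alone, and the list's adjusted p was 6.05e-54, or 0.000653 with an estimated correlation. Insig1 changed by -0.59 ± 0.058 (adjusted p = 1.03e-05), Mvd by -0.60 ± 0.064, Cyp51 by -0.46 ± 0.045 and Idi1 by -0.44 ± 0.051. Of these, Insig1 lies within 100 tested genes of Htt. Interferon response genes rose: 12 of 34 passed, 21 adjusted over the list alone, 0 fell, and the list had an adjusted p of 6.35e-16 (adjusted p = 0.247 with an estimated correlation). Irf7 rose by 0.78 ± 0.10 (adjusted p = 0.000144), Ifih1 by 0.34 ± 0.062 and Xaf1 by 0.32 ± 0.054. Of 29 oligodendrocyte and myelin genes 8 fell and 4 rose, with 15 past the threshold adjusted over the list alone; Tspan2 changed by -0.56 ± 0.043 (adjusted p = 4.61e-07), Aspa by -0.53 ± 0.057 and Mal by -0.50 ± 0.059. Among astrocyte genes 6 of 24 fell and 1 rose (14 adjusted over the list alone), with Agt at -0.50 ± 0.081 and Glul at -0.45 ± 0.045. The microglial gene Itgax rose by 1.35 ± 0.19 (adjusted p = 0.000402). Chdh had the smallest p of the genes that rose, at 1.14 ± 0.077 (adjusted p = 2.59e-07; 29.4 ± 1.98 against 13.4 ± 1.85 CPM, SD), with Cdkn1c at 1.09 ± 0.14 and Acy3 at 0.95 ± 0.10. Car2 changed by -0.73 ± 0.051, Etnppl by -0.71 ± 0.073 and Ngfr by -0.90 ± 0.12. Wild-type female 3 lay apart on the first component (26% of the variance), and its values fell with transcript length (slope of -0.273 log2 per doubling, others -0.0748 to 0.065). Without it 427 of 626 called genes rose. The correlation of the fold change with transcript length was 0.367. With the length and GC trend removed 507 of 789 called genes rose, and the replicate block left 282 genes called.

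In cerebellum (8 against 8), 1272 genes rose and 1300 fell, 51 of them by more than 2-fold (151 genes in all with voom over all tissues). Oligodendrocyte and myelin genes fell: 21 of 29 passed, 23 adjusted over the list alone, 0 rose (adjusted p = 2.37e-19; adjusted p = 0.392 with an estimated correlation). Mal changed by -0.49 ± 0.043 (adjusted p = 1.9e-07), Cldn11 by -0.41 ± 0.042 and Tspan2 by -0.29 ± 0.026. Cholesterol synthesis genes fell in 13 of 24 cases, 16 adjusted over the list alone (adjusted p = 3.97e-06; 0.467 with an estimated correlation), among them Msmo1 at -0.33 ± 0.043 and Fdft1 at -0.28 ± 0.041. Of 18 cerebellar neuron genes 8 fell and 0 rose (9 adjusted over the list alone), by small amounts: Cbln1 at -0.32 ± 0.041, Cbln3 at -0.31 ± 0.04, Neurod1 at -0.20 ± 0.029 and Pvalb at -0.16 ± 0.02. Immediate early genes fell in 7 of 22 cases and 1 rose (12 adjusted over the list alone), with Dusp1 at -0.65 ± 0.13 (adjusted p = 0.00287), Junb at -0.53 ± 0.13 and Ier2 at -0.47 ± 0.088. Among circadian clock genes 3 of 19 fell (9 adjusted over the list alone), including Nr1d1 at -0.33 ± 0.046. Those 3 of 19 are near the share of all tested genes called in this tissue, 16.1%. The genes that fell furthest included Myo15 at -2.58 ± 0.16 (adjusted p = 3.1e-09; 1.18 ± 0.34 against 7.07 ± 1.76 CPM, SD), Car9 at -1.57 ± 0.079 and Ccdc63 at -1.48 ± 0.098. Muc15 rose by 1.18 ± 0.086 (adjusted p = 1.23e-08), Onecut2 by 1.03 ± 0.094, Necab1 by 1.02 ± 0.061 and Tnc by 0.79 ± 0.054. Lamp5, Cbln4 and Glra1 fell by over 2 log2 units, with wild-type levels that varied between libraries (Glra1 5.28 ± 3.23 CPM, SD). Summed transcripts of choroid plexus and ependymal genes varied within both genotypes, from 46 to 2790 CPM in Q175 and from 55.4 to 2310 CPM in wild type.

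In hippocampus (8 against 8), 320 genes rose and 423 fell (76 genes in all with voom over all tissues). Of 23 excitatory neuron genes 5 fell and 0 rose, 10 passed adjusted over the list alone (adjusted p = 3.85e-05; 0.284 with an estimated correlation): Wfs1 changed by -0.70 ± 0.10 (adjusted p = 0.000817), Neurod6 by -0.42 ± 0.063, Camk2a by -0.41 ± 0.053 (3483 ± 293 against 4616 ± 262 CPM, SD) and Nptx1 by -0.35 ± 0.054. Scn4b, from the striatal projection neuron list, fell by 0.75 ± 0.093 (adjusted p = 0.000334), 1 of 4 of that list's 30 members to fall. Immediate early genes fell in 3 of 24 cases, 12 adjusted over the list alone (adjusted p = 2.21e-09; 0.467 with an estimated correlation): Egr2 at -1.20 ± 0.30 (adjusted p = 0.0302), Npas4 at -0.74 ± 0.14 and Arc at -0.69 ± 0.17. Cholesterol synthesis genes fell in 6 of 24 cases, 12 adjusted over the list alone (adjusted p = 3.81e-06; 0.467 with an estimated correlation), among them Insig1 at -0.36 ± 0.08 (adjusted p = 0.0168). The clock genes Per1, Nr1d1 and Per3 fell, at -0.36 ± 0.094, -0.30 ± 0.049 and -0.29 ± 0.069 (5 of 19 adjusted over the list alone). Slc45a3 rose by 1.26 ± 0.16 and Acy3 by 0.83 ± 0.15, while Nhlh1 changed by -1.15 ± 0.16, Mylk3 by -1.07 ± 0.12 and Plk5 by -0.98 ± 0.12. Without Q175 female 2 the count was 1270, without Q175 female 4 it was 484 and without wild-type female 4 it was 494. Q175 females 3 and 4 lay apart on the first component (41% of the variance), and their values fell with transcript length (slopes of -0.37 and -0.27 log2 per doubling, others -0.05 to 0.08). Without both 923 genes were called, 604 of them among the 743, with 8 excitatory neuron, 12 cholesterol synthesis and 4 immediate early genes lower. On the deposited FPKM values 567 of 865 called genes rose. With the lane code as a term, which here only sets 2 Q175 females apart from 14 libraries without a code, 387 genes, 1 cholesterol synthesis gene and 1 immediate early gene were called.

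In hypothalamus/thalamus (8 against 8), 18 genes rose and 78 fell. Oligodendrocyte and myelin genes fell in 8 of 29 cases, 13 adjusted over the list alone, 0 rose (adjusted p = 3.75e-20; 0.413 with an estimated correlation). Mal changed by -0.90 ± 0.12 (adjusted p = 0.00169), Aspa by -0.89 ± 0.12 and Tspan2 by -0.76 ± 0.079. Astrocyte genes fell in 4 of 24 cases, and adjusted over the list alone 14 fell and 3 rose: Glul at -0.43 ± 0.067, Aqp4 at -0.42 ± 0.087 and Sparcl1 at -0.27 ± 0.038. Il33 had the smallest p, at -1.02 ± 0.09 (adjusted p = 7.02e-05; 55.4 ± 5.15 against 113 ± 17.7 CPM, SD), and Car2 fell by 0.90 ± 0.12. Insig1, which lies within 100 tested genes of Htt, changed by -0.42 ± 0.062 and was 1 of 2 cholesterol synthesis genes called. Fads1 changed by -0.22 ± 0.034, and Arc, at -0.50 ± 0.10, was the single immediate early gene called. Cldn14 rose by 1.37 ± 0.15 (adjusted p = 0.000345), Acy3 by 0.93 ± 0.15 and Slc45a3 by 0.67 ± 0.12. In interferon response genes 0 of 32 passed with edgeR and 6 rose adjusted over the list alone. Without wild-type male 2 the count was 226, without wild-type female 3 it was 60 and without Q175 male 4 it was 63; Q175 male 3 held 4630 CPM of choroid plexus and ependymal transcripts against at most 151 CPM elsewhere. The share that rose was larger with other scalings: 107 of 333 with DESeq2, 25 of 85 on FPKM values and 64 of 211 with the length and GC trend removed. Values fell with transcript length in Q175 female 2 (slope of -0.365 log2 per doubling), Q175 female 3 (-0.159), Q175 male 3 (-0.135) and wild-type male 2 (-0.185), against 0.0325 to 0.0957 in the others. These 4 lay to one side on the first component (36% of the variance). Without Q175 female 2 and Q175 male 3 the share that rose was 24 of 104, and 36 genes were called with the lane code as a term.

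**Figure D3:**
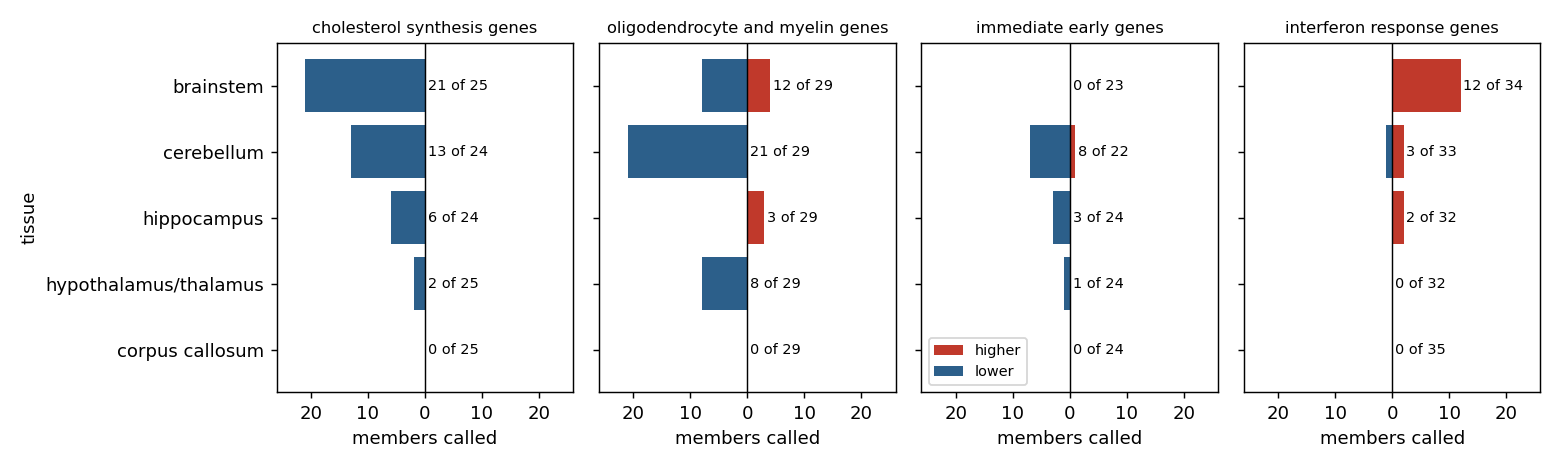
Members of 4 gene lists called higher or lower in Q175 in each brain region, edgeR, with the number called of those tested. Cholesterol synthesis genes fell in 21 of 25 cases in brainstem and 13 of 24 in cerebellum, and interferon response genes rose in 12 of 34 in brainstem.

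In corpus callosum (8 against 8), 8 genes rose and 1 fell. Abhd1 rose by 1.43 ± 0.20 (adjusted p = 0.0128), Smoc1 by 1.05 ± 0.16, Osbpl5 by 0.45 ± 0.067 and Dbhos, whose reads cannot be told from those of a partner on the other strand, by 1.58 ± 0.25; the other 5 called genes carry no established name. With edgeR, 3150 genes had an unadjusted p under 0.05. Interferon response genes lay higher as a list, with a median change of 0.86 (adjusted p = 3.08e-26; 0.413 with an estimated correlation): 0 of 35 passed with edgeR over all genes, 33 passed adjusted over the list alone, and 20 passed with DESeq2. Usp18 had a change of 1.82 ± 0.44 and Bst2 of 1.36 ± 0.31, each at an adjusted p of 0.209. In 29 microglia and macrophage genes 0 passed and 15 passed adjusted over the list alone, with Tmem119 at 0.52 ± 0.10 (adjusted p = 0.171). Immediate early genes lay lower, 0 of 24 passed and 6 adjusted over the list alone, with Npas4 at -1.36 ± 0.32 and Arc at -0.97 ± 0.23. Transcripts of neighbouring tissue differed between the libraries: meningeal genes summed to 129 to 1320 CPM in Q175 and 138 to 278 CPM in wild type, and excitatory neuron genes to 672 to 3010 and 1580 to 3860 CPM. Removing a single library moved the count to 0 (wild-type females 1 and 2), 3 (Q175 female 4, Q175 males 2 and 3, wild-type female 4 and wild-type male 2), 4 (wild-type female 3 and wild-type male 3) or 5 (Q175 female 1 and Q175 male 1), and DESeq2 called 202 genes, of which 156 rose, while voom over all tissues called 1466, of which 460 rose. With the summed excitatory neuron transcripts as a term edgeR called 0 genes, as it did with the lane code, a term that here only sets aside 1 library of each genotype. With the replicate block it called 0 genes too.

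In brown adipose tissue (8 against 8), 790 genes were called, of which 83 rose and the rest fell. Muscle fibre genes made up the largest falls: 21 of 29 passed and 29 passed adjusted over the list alone, with a median change of -3.68 (adjusted p = 1.09e-22; 0.413 with an estimated correlation). Myh7 changed by -4.50 ± 1.18 (adjusted p = 0.0402), Myl2 by -4.37 ± 1.09, Tnni1 by -4.15 ± 1.03, Mb by -3.53 ± 0.77 and Tpm2 by -3.43 ± 0.77. The summed muscle fibre transcripts ran from 351 to 1600 CPM in Q175 and from 485 to 28100 CPM in wild type. Fatty acid and triglyceride synthesis genes rose in 6 of 26 cases, 8 adjusted over the list alone (adjusted p = 6.45e-12; 0.283 with an estimated correlation): Lpin1 by 0.65 ± 0.15 (adjusted p = 0.0198), Aacs by 0.63 ± 0.12, Srebf1 by 0.62 ± 0.15 and Mlxipl by 0.56 ± 0.11. Acot11 rose by 0.88 ± 0.20, Ppp1r3b by 0.77 ± 0.14 and Pnpla3 by 0.62 ± 0.18. Of 21 glycolysis genes 4 rose, Pfkl by 0.62 ± 0.098 and Eno1 by 0.61 ± 0.14 among them, and 3 fell; the list's median was 0.12 and its mean -0.23. Collagen and extracellular matrix genes fell in 12 of 30 cases, 17 adjusted over the list alone (adjusted p = 2.5e-13; 0.395 with an estimated correlation), with Thbs2 at -1.47 ± 0.26 and Dcn at -0.81 ± 0.14. Of 28 macrophage genes 7 fell (10 adjusted over the list alone), with C1qa at -0.68 ± 0.15 and Cd74 at -0.61 ± 0.15. Without the 4 wild-type libraries above 8000 CPM of muscle transcripts 31 genes were called, 2 of them collagen or matrix genes and 0 of the synthesis or macrophage lists, and with the log2 muscle sum as a term 1 gene was called (the list's own median then turned to 0.77, which follows from a term built on its members). The wild-type males kept in the first of these fits still held at least 4360 CPM of muscle transcripts. That fit also had fewer wild-type libraries, so part of the lost calls may be lost power. Removing a single library gave 313 (wild-type female 3), 437 (Q175 male 3), 503 (Q175 male 1, and wild-type male 4), 504 (Q175 male 2) or 1354 genes (wild-type male 1), and the share that rose was 309 of 1383 with DESeq2, 411 of 1154 with the length and GC trend removed, 663 of 1387 with voom over all tissues and 51 of 220 with the lane code as a term. It was smaller on FPKM values (38 of 764) and without a sex term (53 of 663).

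In gonadal white adipose tissue (8 against 7), 2467 genes rose and 2681 fell, which is 32.1% of the 16049 tested. Oxidative phosphorylation genes fell: 57 of 60 passed, 59 adjusted over the list alone, with a median change of -0.52 (adjusted p = 1.2e-54; 0.247 with an estimated correlation). Atp5k changed by -0.69 ± 0.074 (adjusted p = 0.000294), Ndufb10 by -0.67 ± 0.074 and Cox7c by -0.64 ± 0.072. Proteasome genes fell in 27 of 34 cases, 28 adjusted over the list alone (adjusted p = 1.71e-14; 0.413 with an estimated correlation), such as Psmd4 at -0.52 ± 0.057 and Psmc1 at -0.37 ± 0.046. Fatty acid oxidation genes fell in 15 of 31 cases and 1 rose (18 adjusted over the list alone), with Hadh at -0.51 ± 0.079, and 8 of 26 fatty acid and triglyceride synthesis genes fell (8 adjusted over the list alone), with Dgat1 at -0.76 ± 0.11. Microglia and macrophage genes rose in 17 of 29 cases, 19 adjusted over the list alone (adjusted p = 5.11e-07; 0.575 with an estimated correlation): Itgam by 1.21 ± 0.25 (adjusted p = 0.0033), Csf1r by 0.89 ± 0.18 and Cd74 by 0.60 ± 0.11. Collagen and extracellular matrix genes rose in 15 of 30 cases, 16 adjusted over the list alone (adjusted p = 5.89e-06; 0.593 with an estimated correlation), with Fn1 at 1.63 ± 0.37 and Bgn at 0.88 ± 0.16. The largest rises were male reproductive tract transcripts, Serpina1f at 11.2 ± 1.56 and Crisp1 at 10.4 ± 1.49 (adjusted p = 0.000513 and 0.000553), whose list summed to 239 to 3420 CPM in Q175 males and 1.66 to 38.2 CPM in wild-type males. In females alone 583 genes were called, 454 of them higher, with 29 of 60 oxidative phosphorylation genes lower at a median of -0.48. The female change in the interaction model, which takes its spread from both sexes, was called for 949 genes, 500 higher and 449 lower. Lane code L1 held 4 wild-type libraries, every wild-type female among them, and 0 Q175 libraries. Genotype and lane are therefore not separated in females. The fit with the lane code rests on wild-type males 1, 3 and 4, which share a code with Q175 libraries. With the lane code as a term 561 genes were called, 25 of 60 oxidative phosphorylation genes fell at a median of -0.37, and 3 proteasome, 1 collagen and 0 macrophage genes were called. The slope of values with transcript length was positive in 7 of 8 Q175 libraries (up to 0.131 log2 per doubling) and negative in 6 of 7 wild-type libraries (down to -0.133). It also went with the lane code. The exceptions, Q175 female 1 (-0.135) and wild-type male 3 (0.032), had the sign of the other libraries of their codes, L8 and L2. Each L1 library was negative, and in L3 the sign differed by genotype. Genotype and lane are thus not separated for this slope. With the length and GC trend removed 4879 genes were called, 3689 of them among the 5148. They include 54 oxidative phosphorylation and 19 proteasome genes that were lower, and 20 macrophage and 12 collagen genes that were higher. On the deposited FPKM values 5007 of 5945 called genes rose.

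In intestinal white adipose tissue (8 against 8), edgeR called 0 genes, with 1297 at an unadjusted p under 0.05; DESeq2 called 11 and voom over all tissues 4547. The simulated test recovered 18 of 100 genes changed 1.5-fold and 44 of 100 changed 2-fold, so changes of that size were mostly not detectable. As a list, oxidative phosphorylation genes lay lower with a median of -0.42 (adjusted p = 4.63e-21; 0.575 with an estimated correlation) and fatty acid oxidation genes with a median of -0.44 (adjusted p = 1.97e-07; 0.613 with an estimated correlation), while 0 of 60 and 0 of 31 members passed, adjusted over the list alone as well. B cell and immunoglobulin transcripts summed to 128 to 10500 CPM in Q175 and 1710 to 7430 CPM in wild type, with the list higher (adjusted p = 0.00514; 0.765 with an estimated correlation). A difference in carried lymphoid tissue is thus not separated from these lists. Pancreas genes summed to 49200 CPM in wild-type female 2 and 11800 CPM in wild-type male 1, and intestine genes to 16500 CPM in wild-type female 2 and 12300 CPM in wild-type male 4, against at most 168 and 235 CPM in Q175. The lists' median changes were -8.3 and -7.36, with 16 of 16 and 12 of 13 members lower adjusted over the list alone and 0 over all genes. Without these 3 libraries edgeR called 0 genes, and without Q175 male 1 it called 1.

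In skin (8 against 6), 412 genes rose and 665 fell. Epidermal genes rose in 7 of 27 cases, and adjusted over the list alone 14 rose and 1 fell (adjusted p = 8.59e-07; 0.247 with an estimated correlation): Krt1 by 0.97 ± 0.17 (adjusted p = 0.0137; 3083 ± 765 against 1562 ± 309 CPM, SD), Hrnr by 0.92 ± 0.23, Krt5 by 0.72 ± 0.14 and Krt14 by 0.72 ± 0.15. Endothelial and mural cell genes fell in 7 of 19 cases, 12 adjusted over the list alone (adjusted p = 4.11e-08; 0.467 with an estimated correlation): Acta2 at -1.26 ± 0.20, Tagln at -1.25 ± 0.26 and Esam at -0.99 ± 0.20. White adipocyte and lipolysis genes fell in 8 of 28 cases, 12 adjusted over the list alone (adjusted p = 2.2e-06; 0.613 with an estimated correlation), with Fabp4 at -1.03 ± 0.17 and Lpl at -0.85 ± 0.18, and Col4a1 fell by 0.91 ± 0.18. Krt18 changed by -5.49 ± 0.84 and Krt19 by -2.61 ± 0.52, among 4 of 9 mammary gland genes that fell (7 called adjusted over the list alone). The summed transcripts of that list overlapped, at 693 to 833 CPM in Q175 and 634 to 870 CPM in wild type, so no loss of mammary tissue is shown. Hair follicle and hair shaft genes fell in 5 of 21 cases with a median change of -6.99 (18 adjusted over the list alone), Krt35 at -9.19 ± 2.33 among them; wild-type males 1 and 2 held up to 53600 CPM of these transcripts and no other library more than 97.2 CPM. Without these 2 libraries 1128 genes were called, 481 of them among the 1077. The hair median then was -0.00857 with 0 members called, Krt86 turned from -9.92 to 0.38, and 15 endothelial, 19 adipocyte and 5 epidermal genes were called. Removing a single library gave 126 (wild-type male 2), 223 (Q175 male 3), 240 (Q175 male 1), 241 (Q175 female 1), 284 (Q175 male 4), 438 (Q175 female 4), 548 (wild-type female 3) or 2065 genes (wild-type male 3), and the share that rose was 421 of 803 on FPKM values, 1026 of 1876 with the length and GC trend removed and 2268 of 3879 with voom over all tissues. The lane code as a term left 263 genes called. With the replicate block 0 were called, though replicate numbers do not pair the animals. Q175 female 4, whose Htt and Abhd1 did not lie at the Q175 level, is counted as Q175 here except in the fit without it.

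**Figure D4:**
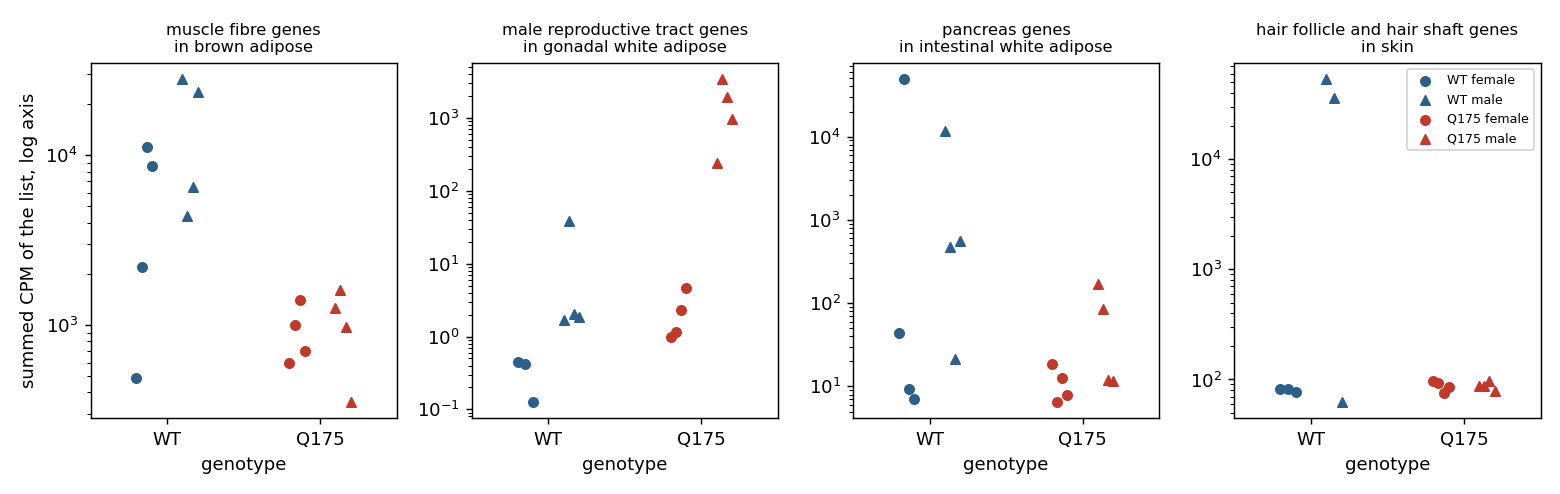
Summed CPM (log axis) of the transcripts of muscle fibre, male reproductive tract, pancreas and hair lists in each library of 4 tissues, by genotype and sex. Muscle sums reach 28100 CPM in wild-type brown adipose, male tract sums 3420 CPM in Q175 gonadal adipose, pancreas sums 49200 CPM in wild-type intestinal adipose and hair sums 53600 CPM in wild-type skin.

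In heart (8 against 8), 3 genes rose and 5 fell. Abhd1 rose by 2.71 ± 0.30, Syde2 by 0.37 ± 0.065 (adjusted p = 0.0408) and Ndrg4 by 0.34 ± 0.051 (adjusted p = 0.0127; 276 ± 19.6 against 219 ± 17.9 CPM, SD). Htt changed by -0.45 ± 0.04, Trim7 by -0.49 ± 0.084, Gnb3 by -0.44 ± 0.076, the sodium channel gene Scn4a by -0.44 ± 0.075 and Nabp1 by -0.33 ± 0.053. No fixed list with at least 5 tested members had a member called over all genes. As a list, fatty acid and triglyceride synthesis genes lay higher (adjusted p = 4.26e-07; 0.467 with an estimated correlation), with 4 of 26 higher and 1 lower adjusted over the list alone. Removing a single library gave 3 genes (Q175 female 2, Q175 male 1, wild-type females 3 and 4, wild-type male 4), 4 (Q175 female 3, Q175 male 2, wild-type male 2) or 5 (Q175 females 1 and 4, wild-type male 3). DESeq2 called 84 genes, of which 47 rose. On FPKM values 2 of 3 called genes rose, with voom over all tissues 6 of 6 rose (1 of them among the 8), and with the replicate block 9 of 13 rose (5 among the 8).

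In gastrocnemius (8 against 8), Abhd1 rose by 2.17 ± 0.34 (adjusted p = 0.0447), Htt fell by 0.40 ± 0.045, and 2310065F04Rik, named here after its values were seen, fell by 0.71 ± 0.11 (adjusted p = 0.0381). Immediate early genes lay lower as a list, with a median change of -0.67 (adjusted p = 2.25e-19; 0.194 with an estimated correlation): 0 of 21 passed over all genes and 10 fell adjusted over the list alone, with Fosb at -2.58 ± 0.44 (adjusted p = 0.0779) and Arc at -1.55 ± 0.28 (adjusted p = 0.113). Muscle fibre genes had a median change of -0.14, with 0 of 29 past the threshold and 1 adjusted over the list alone. With edgeR 888 genes had an unadjusted p under 0.05, and DESeq2 called 17, of which 3 rose. The count was 1 without any one of 11 libraries: Q175 females 1 to 4, Q175 males 3 and 4, wild-type females 1 and 2, and wild-type males 1, 3 and 4. The model without a sex term, that with the lane code and that with the replicate block each called 0 genes. On FPKM values 2 of 2 called genes rose.

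Across tissues, 17 genes were called in 4 or more tissues with a single direction. Beside Abhd1, Galnt11 rose in 6 tissues (0.19 to 0.41), Insig1 fell in 5 (-0.84 to -0.36) and Tmeff1 fell in 5 (-1.17 to -0.23), while Cd82, Osbpl5, Pla2g4a and Gng12 rose in 4 and Car2, Aspa, Agt and Pex5l fell in 4. Abhd1, Galnt11 and Insig1 lie within 100 tested genes of Htt. Smoc1 rose in 5 tissues and fell in 1, and Acy3 rose in 4 and fell in 1. By the voom fit over all tissues, the change differed between tissues in 6287 of 20662 genes (30.4%). Among them were Galnt11 (adjusted p = 0.00183) and Insig1 (adjusted p = 0.00145). That fit shares the spread of each gene between tissues. It called 4547 genes in intestinal adipose and 151 in cerebellum, where edgeR called 0 and 2572. The 6287 genes and these p-values carry that limit, and transcripts carried from other tissues were not removed from them. Among brain regions, brainstem and cerebellum shared 48 genes that rose and 92 that fell, against 26.8 and 12.9 for independent lists. Brainstem and hypothalamus/thalamus shared 11 and 42, against 0.374 and 0.772, and cerebellum and hypothalamus/thalamus 7 and 58, against 1.37 and 6.23. Brainstem and hippocampus shared 52 and 14, against 6.44 and 3.97, and cerebellum and hippocampus 55 and 108, against 24 and 32. Hippocampus and hypothalamus/thalamus shared 8 and 10, against 0.33 and 1.95. Genes called in opposite directions numbered 50 for cerebellum and hippocampus, 20 for brainstem and cerebellum, 5 for brainstem and hippocampus, 2 for cerebellum and hypothalamus/thalamus and 0 in the other pairs. The regions come from the same 16 animals, so an animal's own deviations enter both lists. Other splits of the animals gave 0 shared calls in each pair. But they called few genes in most regions (at most 0 in brainstem, 303 in cerebellum, 3 in hippocampus and 10 in hypothalamus/thalamus), so how far the shared animals raise the overlaps is not measured. Immediate early genes had an unadjusted list p under 0.05 and a lower direction in 9 of 11 tissues, and a median change below 0 in 11.

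The response to genotype was compared between sexes in each tissue. In gonadal white adipose tissue the difference passed for 37 genes. Spry4 rose by 0.44 in females and fell by 0.91 in males (adjusted p of the difference = 0.0041). Ank3 had a change of -0.15 in females and 3.06 in males, Kcnd3 of -0.68 and 1.96 and Fads2 of -0.58 and 3.48. In 31 of the 37 the change was larger in size in males, and in 23 it was higher in males than in females. Q175 males held 239 to 3420 CPM of male reproductive tract transcripts and wild-type males 1.66 to 38.2 CPM. Whether carried tract tissue accounts for the rises in males was not tested. That 0 of the 37 are on that list does not bear on it. The list summed to at most 4.69 CPM in females, which leaves its genes little to compare between sexes. In the other 10 tissues edgeR called 0 genes, with between 244 (intestinal adipose) and 3532 (hippocampus) at an unadjusted p under 0.05. DESeq2 called 47 in brown adipose, 47 in hippocampus, 29 in hypothalamus/thalamus, 1 in heart, 447 in skin and 0 in the rest, and 613 in gonadal adipose. In skin only wild-type males 1 and 2 held hair transcripts (up to 53600 CPM). In hippocampus only Q175 females 3 and 4 had steep slopes with transcript length (-0.37 and -0.27). Whether these libraries account for the skin and hippocampus values was not tested, so they are not shown to be responses that differ by sex.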

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

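Of the tests in this part, those of skeletal muscle, of the length and GC trend and of male reproductive tract tissue were chosen only after the result was seen. A library was singled out where its value stood apart from the other 3 of its group of 4 (Dixon's test). Chance flags about 1 in 20 groups, so 6.25 of the 125 groups of 4 would stand apart by chance, and 18 did.

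Library totals, in M (mega) counts, stood apart in brainstem Q175 female 3 (38.4 M, the others 32.6 to 33.2), corpus callosum wild-type male 3 (39.7 M, the others 33.4 to 33.8) and gastrocnemius Q175 female 4 (44.3 M, the others 39.5 to 39.8). Htt stood apart in 7 libraries. In brown adipose it was 29.9 CPM in Q175 female 1 (the others 26.1 to 26.6) and 16.5 CPM in wild-type male 1 (42.2 to 45.1), and in gonadal adipose 35.1 CPM in Q175 female 1 (59.1 to 60.8). It was 75 CPM in intestinal adipose wild-type male 4 (95.4 to 99.6), 95.9 CPM in brainstem wild-type female 3 (176 to 188), 124 CPM in hypothalamus/thalamus Q175 male 3 (187 to 188) and 67.1 CPM in skin Q175 female 4 (37.1 to 40.5). Abhd1 in that skin library also lay within the wild-type range (2.22 CPM on the TMM scale), so its genotype label is in doubt and was not tested. Among the libraries with low Htt, values fell with transcript length in brown adipose wild-type male 1 (slope of -0.246 log2 per doubling) and gonadal adipose Q175 female 1 (-0.135). They also fell in brainstem wild-type female 3 (-0.273) and hypothalamus/thalamus Q175 male 3 (-0.135), but not in intestinal adipose wild-type male 4 (0.00241). Whether this slope accounts for their Htt was not tested. Transcripts of other tissues stood apart in 8 cases. Male reproductive tract genes summed to 38.2 CPM in gonadal adipose wild-type male 2 (1.66 to 2.03). In intestinal adipose, pancreas genes summed to 49200 CPM in wild-type female 2 (7.01 to 43.9) and 11800 CPM in wild-type male 1 (21.1 to 554), and intestine genes to 235 CPM in Q175 female 3 (191 to 198), 16500 CPM in wild-type female 2 (104 to 148) and 12300 CPM in wild-type male 4 (153 to 174). Choroid plexus and ependymal genes summed to 4630 CPM in hypothalamus/thalamus Q175 male 3 (115 to 129) and 1670 CPM in cerebellum wild-type male 4 (55.4 to 59.6).

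Muscle fibre genes were lower in Q175 brown adipose. Skeletal muscle carried in wild-type libraries is a candidate explanation: of 177 genes abundant in gastrocnemius and scarce in brown adipose, 100% were lower in Q175, with a median change of -3.38 (quartiles -3.65 and -2.32). Of the genes called lower, 421 (59.5%) were at least 5 times higher in gastrocnemius, against 5.07% of the genes tested. With the lane code as a term the list's median was -3.93, which, if that code marks the lane, argues against the lane as the whole cause. Muscle was not carried in every wild-type library, as the lowest held 485 CPM against 351 to 1600 CPM in Q175. Why several wild-type libraries held more was not tested, and the part of genotype, dissection and housing was not tested.

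Oxidative phosphorylation genes were lower in Q175 gonadal adipose, with a median of -0.52 and 57 of 60 called. With the trend of length and GC content removed, 54 were called lower, which argues against that trend as the whole cause. Male reproductive tract tissue in Q175 male libraries could not account for the fall in females, where the median was -0.48. All wild-type females carry lane code L1 and no Q175 female does, so genotype and lane are not separated in females. With the lane code as a term the median was -0.37, with 25 of 60 called. That fit had 8 residual degrees of freedom, and lane L1 held 0 Q175 libraries. On the same reading of the code, the value argues against the lane alone. It rests on wild-type males 1, 3 and 4, the wild-type libraries that share a code with Q175 libraries. Q175 males carried tract transcripts, so lane and tract tissue acting together are not excluded. Genotype, housing, colony and the share of cell types in the tissue stay open and were not tested.

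The response to genotype differed between sexes for 37 genes in gonadal adipose. Between tissues it differed for 6287 genes by the voom fit, which shares the spread of each gene between tissues. For the sexes 1 of 100 splits of the animals, the real one, gave as many genes, the highest other split giving 32. For the tissues it was 1 of 40 splits, the highest other split giving 1836.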

How the results depend on the processing

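The alternatives that leave out or weigh libraries with transcripts of other tissues, that leave out libraries standing apart, that fit females alone or that remove the length and GC trend were chosen after seeing the data; the others were fixed before. Replicate numbers do not pair the animals: the correlation of same-numbered libraries passed 0.1 in 0 of 8 pairs in brainstem up to 6 of 8 in intestinal adipose (lowest -0.416, highest 0.719), and 55 of 170 libraries correlated best with their own number. With the replicate block the counts were 170 in brown adipose, 2877 in gonadal adipose, 282 in brainstem, 409 in hippocampus, 12 in hypothalamus/thalamus, 13 in heart and 0 in corpus callosum, gastrocnemius and skin, and no other tissue moved by over 1.5 times. Where counts below move with a setting, the cause was not tested.

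DESeq2 called 1383 genes in brown adipose (786 of them also called by edgeR), 11 in intestinal adipose, 1271 in hippocampus (736 shared), 333 in hypothalamus/thalamus, 202 in corpus callosum, 17 in gastrocnemius, 84 in heart and 2911 in skin (1077 shared). For the difference between sexes DESeq2 called 47 genes in brown adipose, 613 in gonadal adipose, 47 in hippocampus, 29 in hypothalamus/thalamus, 1 in heart and 447 in skin. The skin and hippocampus counts carry the limit given above, of libraries of a single sex that stand apart. Without a sex term the counts were 3402 in gonadal adipose, 0 in gastrocnemius and 4 in heart. With the lane code as a term they were 220 in brown adipose (158 shared), 561 in gonadal adipose (431 shared), 387 in hippocampus, 36 in hypothalamus/thalamus, 0 in corpus callosum, 0 in gastrocnemius, 3 in heart and 263 in skin (262 shared). On FPKM values heart had 3. Voom over all tissues, which shares the spread of genes between tissues, called 1387 in brown adipose (663 of them higher), 4547 in intestinal adipose (2636 higher), 84 in brainstem, 151 in cerebellum, 76 in hippocampus, 173 in hypothalamus/thalamus (55 higher), 1466 in corpus callosum (460 higher), 8 in gastrocnemius and 3879 in skin (2268 higher). With the length and GC trend removed the counts were 789 in brainstem (470 shared), 1271 in hippocampus, 211 in hypothalamus/thalamus and 1876 in skin (1050 shared); the correlation of the fold change with transcript length was 0.367, -0.439, -0.415 and 0.123 in these, and 0.329 in gonadal adipose.

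Brown adipose had 31 genes without 4 muscle-rich wild-type libraries and 1 with the muscle fibre sum as a term. Gonadal adipose had 583 in females only and 1118 with the male reproductive tract sum as a term. Intestinal adipose had 1 with the B cell sum as a term, and corpus callosum 0 with the excitatory neuron sum as a term. Genes called in several tissues numbered 144 for at least 3 tissues, 4 for at least 5 and 58 with DESeq2, against 17. List tests passing numbered 1 with an estimated correlation against 166. The difference between tissues was called for 5819 genes without the animal term and 6085 with a floor on CPM, against 6287.

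Leaving out each library in turn gave 313 to 1354 genes in brown adipose, 3979 to 5998 in gonadal adipose, 0 to 1 in intestinal adipose, 366 to 626 in brainstem, 2091 to 2638 in cerebellum, 484 to 1270 in hippocampus, 60 to 226 in hypothalamus/thalamus, 0 to 12 in corpus callosum, 1 to 4 in gastrocnemius, 3 to 10 in heart and 126 to 2065 in skin. Of 177 results for single genes, some of them not named here, 162 were called, 156 of these kept their direction in every setting and 6 turned in at least 1. With the muscle fibre sum as a term Myh7 turned to 0.54, Myl2 to 0.0102, Tnni1 to 0.42, Mb to 0.47 and Tpm2 to 0.59: these 5 are members of the list summed, so the loss of their change is built into that term. Krt86 in skin turned to 0.38 without the libraries with hair transcripts, which were chosen by a list that holds it, and Htt in gonadal adipose, which was not called, to 0.0723 on FPKM values. Of the 162 calls, 51 were lost with the replicate block, 48 with the lane code, 61 with voom, 15 on FPKM values and 0 with RLE size factors, and 257 of the 2766 fits that left out a library, uncalled results included, lost a call.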

Other observations

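In this part, the test of alleles linked to Htt was chosen only after the result was seen, and so were the single male described next and the 3 lists followed across tissues. Genes near Htt in gene order were among those moved in most tissues. Of 7 genes other than Htt that moved the same way in 8 or more tissues at an unadjusted p under 0.05 (1 of the 7 also moved the other way in 1 tissue, and it lies elsewhere), 3 lie within 100 tested genes of Htt, where 0.116 are expected (one-sided Fisher exact p = 0.000151), and the highest number in another window of that size was 1. With 7 or more tissues it was 4 of 22 (0.366 expected), as many as the highest other window, which held 4, and with 6 or more tissues 5 of 64 (1.06 expected), where another window also held 5. Alleles linked to the modified Htt and carried along with it are a candidate explanation for the rises of Abhd1 and Galnt11. These rises differ in size between tissues by the voom fit. A local effect of the modified locus is another candidate. The counts cannot separate them, so they cannot be told apart here, as the deposited tables hold no sequence variants.

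In a single Q175 male Abhd1 was the lowest of the Q175 values and within the wild-type range in 11 of 11 tissues. If a crossover had replaced the segment beyond Abhd1 in that animal, genes farther out would be nearer the wild-type mean. That held in 19 of 33 pairs of gene and tissue for Galnt11, Insig1 and Prkag2, against 3 to 11 in the other 7 Q175 mice. The bound set before these pairs were counted was 22, so the question stays open. By gene, the male was nearer the wild-type mean in 8 tissues for Galnt11 (at most 2 in another Q175 mouse), 7 for Prkag2 (at most 5) and 4 for Insig1 (at most 5). For Atraid, which lies between Abhd1 and Htt, it was 7 (at most 5), so where a crossover would lie is not settled either. A test would be genotypes of markers on both sides of Htt in the 16 animals, or reads with variants of another strain. A second prediction is that Abhd1 follows such a marker and not the repeat.

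Cholesterol synthesis genes lay lower in 6 tissues at an unadjusted list p under 0.05, immediate early genes lower in 9 and interferon response genes higher in 5. As many tissues in either direction came from 6 of 100 splits of the animals for immediate early genes (real 9, highest other 10), 23 of 100 for cholesterol synthesis (real 6, highest other 8) and 56 of 100 for interferon response (real 5, highest other 9). Chance is not excluded for any of these 3 as patterns over tissues. The tissues come from the same animals, so the state of an animal may enter many of them. Handling before death and the order of dissection are untested candidates for the immediate early genes, and recorded times of death would allow a test.

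Other splits of the animals measured how often a count as large arises. In each of these 8 tissues 1 of 100 splits, the real one, gave as many genes: brown adipose (real 790, highest other 197), gonadal adipose (5148 and 1), brainstem (509 and 0), cerebellum (2572 and 303), hippocampus (743 and 3), hypothalamus/thalamus (96 and 10), heart (8 and 0) and skin (1077 and 0). With 100 splits the smallest share possible is 1 of 100. Other splits mix the genotypes, so a real difference widens their spread and lowers their counts. In gonadal adipose 50 of the other splits kept the group sizes. The splits cannot tell genotype from dissection, housing or colony, so chance differences in carried tissue are not excluded. In corpus callosum 2 of 100 splits gave as many (real 9, highest other 2392) and in gastrocnemius 2 of 100 (real 3, highest other 1746). In each of these 2 tissues a single other split called many times the real count and the next highest called 0, which points to a structure of the samples. What the structure is was not tested. In intestinal adipose the real count of 0 is reached by any split (100 of 100 splits), and a single other split called 4550. Genes called in 4 or more tissues came from 1 of 100 splits (real 17, highest other 0). List calls came from 2 of 100 splits (real 166, highest other 183).

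For the difference between sexes the real count was 0 in 10 tissues, which any split reaches (100 of 100 splits), so the splits say nothing on chance there. The highest other counts were 37 in brown adipose, 0 in intestinal adipose, 2 in brainstem, 14 in cerebellum, 1 in hippocampus, 803 in hypothalamus/thalamus, 0 in corpus callosum, 5 in gastrocnemius, 139 in heart and 2 in skin. In gonadal adipose 1 of 100 splits gave as many (real 37, highest other 32). Splits with 803 and 139 genes in hypothalamus/thalamus and heart point to a structure of the samples there, which was not tested.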
